A study of Mus musculus with 12 samples.

How the data were processed

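RNA was measured in whole hearts of 12 male C57BL/6 mice. In cardioGRMRdKO mice a Cre recombinase driven by the αMHC promoter, which is active in cardiomyocytes, recombines floxed alleles of both the glucocorticoid receptor gene (Nr3c1) and the mineralocorticoid receptor gene (Nr3c2). The controls, called dflox, were littermates that carried the floxed alleles and no Cre. Each genotype was sampled at 1 and 2 months of age with 3 hearts per group. The design text counts mice, so each array stands for a separate animal. Every cardioGRMRdKO heart carried Cre and no dflox heart did, and hearts with Cre and unfloxed receptor genes were not part of the comparison, so effects of the receptor loss and of Cre itself are measured together. The labels do not state which exons are deleted.

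Per the labels, total RNA was purified on columns with DNase treatment, and 500 ng was used to make Cy3-labelled cRNA for Agilent whole mouse genome arrays, 4 arrays to a slide. The authors read the arrays with Agilent Feature Extraction (9.5 per the labels, 9.5.3.1 per the file headers). The deposited scanner files give for each spot a processed signal, an intensity on a linear scale from which the software had subtracted local background and spatial trends within the array. The deposited series matrix holds the same intensity: its 45018 values per array equal the processed signal of the same spot in 100% of cases, with array medians from 48.0 to 87.6, and no scaling between arrays had been applied. Probe coordinates are those of the file headers, on mouse build mm7. The build's annotation was not at hand, so exons and UTRs are not given.

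Each array has 43379 spots for transcripts and 1639 control spots. The signal of 27649 to 31202 transcript spots per array (63.7 to 71.9%) was well above background by the scanner software's own criterion. The software marked 67 to 241 spots per array as outliers and found 0 saturated. The 75th percentile of intensity ran from 465 to 1068 between arrays. The number of hearts limits the precision of every comparison.

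Control spots and outlier spots were left out. Signals were put on a log2 scale, each array's 75th percentile over transcript spots was subtracted, and spots of one probe were averaged, so a level of 0 is the array's 75th percentile. Of 41174 probes, 26979 were kept because they were well above background on all 3 arrays of at least 1 group. Probes took current gene symbols through their RefSeq accession (22951 probes), another accession of the probe (124) or an older symbol (3077). For 6582 the name in the file was already current, and for 8440 the file's own name was kept. Where several probes of a gene passed, as in 6241 genes, the brightest represented it. This left 18258 genes, of which 476 lacked a value on at least 1 array and 17782 had all values.

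A linear model with the 4 group means was fitted to all 12 arrays with limma 3.58.1 (R 4.3.3, package data.table, version 1.17.8), with moderated variances (prior degrees of freedom 2.22, residual degrees of freedom 8). The comparisons were cardioGRMRdKO against dflox at 1 month, at 2 months and averaged over both ages, the difference between the genotype effects at the 2 ages, and 2 months against 1 month in each genotype. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. An exact permutation test of 3 hearts against 3 cannot give a p under 0.10, so single genes were tested with limma, whose adjusted p values are the ones printed. Errors are given as SD of the replicates for levels and as SE from limma for log2 differences.

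Shifts of 31 gene lists were tested against all other genes with limma's camera, with a preset correlation of 0.01 between genes, on the 17782 genes with all values, and adjusted over the lists within a comparison. A list was tested again with the correlation estimated from the residuals and with limma's fry, which asks whether a list's genes move on balance one way without comparing them with other genes. The medians given for a list are medians of log2 differences over its tested members.

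The lists, the comparisons, the main settings and the rule for named genes were fixed before the data were examined. Named genes are the 10 largest rises and 10 largest falls among called genes for the genotype comparison at each age and for the age comparison in dflox, and the 5 next largest each way for the averaged comparison. They had to be well above background on all arrays of the brighter group, have replicates that did not overlap between groups, and carry a gene name. Nr3c1, Nr3c2, Nppa, Nppb, Acta1, Myh6, Myh7, Fkbp5, Per1, Sgk1, Tsc22d3, Ryr2, Ptgds and Klf15 were always named, as were up to 4 members of each list with the smallest p. A few genes that met this rule are not reported here. Lists of airway epithelium, lung alveolus, cartilage and neutrophil markers were added after the arrays had been looked at.

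Where a gene was well above background on none of the dimmer group's arrays, its change in the main setting is given as at least N-fold. This bound sets the brighter group's mean against the dimmer group's mean after raising each of its arrays to the lowest signal among that array's probes that were well above background, where the gene's own value was lower.

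The pipeline was tested on simulated data with each gene's mean and residual SD and no correlation between genes, with changes planted in the 2-month cardioGRMRdKO arrays in 5 runs of 17782 genes. In the 2-month genotype comparison limma called 20.9% of 339 genes changed by 1.5-fold, 60.5% of 329 changed by 2-fold and 83.4% of 332 changed by 4-fold, with 5.2 false calls per run. For the difference between the ages those shares were 2.06, 30.7 and 73.8%, with 2.6 false calls. A list of 20 genes shifted by 0.5 was called in 5 of 5 runs in both, and no unchanged list was called. Since the simulated genes were independent, these runs do not show how often camera calls unchanged lists of correlated genes. On the real arrays, other splits of the hearts into groups of the same sizes called a median of 4 to 10 lists, depending on the comparison.

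The alternatives covered normexp background correction with an offset of 50, other scalings, other filters and probe summaries, slide or replicate number as terms of the model, other variance models, array weights, each array left out in turn, and the list tests above. After the data had been seen, the place of an array on its slide, an airway marker score and the omission of slide 3 were added. The mean of the macrophage list was also fitted by an ordinary linear model of the group means and place or the airway score, for its 95% interval. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.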

Results

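Gene expression was measured on 12 arrays, 1 per heart, from cardioGRMRdKO and dflox mice at 1 and 2 months of age, with 3 hearts in each of the 4 groups. The cardioGRMRdKO hearts, called knockout hearts here, came from mice in which Cre acts on both corticosteroid receptor genes in cardiomyocytes. Per array, 63.7% to 71.9% of transcript spots were well above background. The arrays lay on 3 slides of 4 places each. Slides 1 and 2 held both genotypes at 1 month, and slides 1 and 3 held both at 2 months. At 1 month every dflox array had an outer place on its slide and every knockout array an inner place, so place and genotype cannot be told apart at that age.

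Nr3c1, the glucocorticoid receptor gene, was measured on its brightest probe (chromosome 18, 39787242 to 39787301, mm7). Every knockout heart with a usable spot was lower there than every dflox heart with one. At 2 months its log2 level was 1.44, 1.15 and 1.18 in the knockout hearts and 2.51, 2.18 and 2.39 in the dflox hearts. It fell 2.15-fold, a log2 difference of −1.10 (SE 0.137, n = 3 and 3, adjusted p = 0.00565). At 1 month the probe had usable spots in 2 hearts per genotype, at 1.35 and 1.51 in knockout and 2.27 and 2.05 in dflox hearts, a difference of −0.73 that did not pass the test (adjusted p = 0.119). Averaged over the ages the difference was −0.92 (SE 0.109, adjusted p = 0.00232). The other 3 Nr3c1 probes that passed the filter gave −0.68, −0.94 and −0.83 at 1 month and −0.26, −0.84 and −0.74 at 2 months, none of which passed the test at a single age. On each of these 3 probes the genotypes overlapped, with knockout 2-month replicate 3 above dflox 2-month replicate 3. Nr3c2, the mineralocorticoid receptor gene, was dim. Its 1 probe that passed the filter (chromosome 8, 75452671 to 75452730) gave 0.06 at 1 month and −0.46 at 2 months (SE 0.499 at each age), and neither passed the test (adjusted p = 0.651 at 2 months). A probe outside the deleted exons does not report on the deletion, and whole hearts also hold cells in which αMHC-Cre is not active.

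The first comparison set knockout against dflox hearts at 1 month. Myh7, the slow β-myosin heavy chain of fetal mouse ventricle, was 12.2-fold higher in knockout hearts, at a log2 level of 7.26 ± 0.138 against 3.65 ± 0.098 (SD, n = 3 each). Casq1, the calsequestrin of skeletal muscle, Nos1, the neuronal nitric oxide synthase, and Gdf15, a stress-induced cytokine, rose 4.49-fold, 4.14-fold and 3.65-fold. Agt, which encodes angiotensinogen, and the potassium channel subunit gene Kcnv2 fell 5.11-fold and 5.19-fold. In all, limma called 179 of 18258 genes, 80 higher and 99 lower, of which 97 differed by 2-fold or more.

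Among the 10 largest rises at 1 month, Myh7 stood at 3.61 (log2, SE 0.178, adjusted p = 2.52e-05; probe on chromosome 14, 49837275 to 49837334), Casq1 at 2.17 (SE 0.206, adjusted p = 0.00133; chromosome 1, 172180644 to 172182147), Nos1 at 2.05 (SE 0.234, adjusted p = 0.00268) and Gdf15 at 1.87 (SE 0.194, adjusted p = 0.00181; chromosome 8, 69084712 to 69084771). Fgf6, a fibroblast growth factor of skeletal muscle, was well above background on 0 of 3 dflox arrays and rose at least 3.16-fold (adjusted p = 0.00107). Mylpf, a fast skeletal myosin light chain, rose by 1.74 (adjusted p = 0.0132), the water channel gene Aqp8 by 1.98 (0.0234), Meig1 by 1.87 (0.0053), Lman1l by 1.76 (0.00532) and Ephx4 by 2.26 (0.0333), the last well above background on 1 of 3 dflox arrays. The largest fall was that of Sds, the gene of serine dehydratase, at −3.56 (SE 0.256, adjusted p = 5.18e-04), with 2 of 3 knockout arrays well above background. Lrat, which esterifies retinol, fell by 3.14 (adjusted p = 0.00618) and the acyl-CoA synthetase gene Acsm5 at least 4.54-fold (0.00793). The cyclic nucleotide-gated channel gene Cngb3 fell by 2.48 (adjusted p = 0.00142), Kcnv2 by 2.38 (0.00133), Agt by 2.35 (0.00107), while Csdc2 fell by 2.25 (0.00104), Tent5b by 2.24 (0.0314) and Ankrd63 at least 2.34-fold (0.0161). These genes were named on the condition that the 3 knockout hearts did not overlap the 3 dflox hearts. Of all genes tested, 18.9% had groups that did not overlap, where chance gives 10%.

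All 179 called genes with a value kept their sign within slide 1 and all 178 within slide 2. These are the hearts that made the calls, 1 or 2 per group and slide, so kept signs decide nothing. With slide as a fixed term 121 genes were called. The count fell to 85, 93 and 100 without dflox 1-month replicates 1, 2 and 3, and to 89, 93 and 82 without knockout 1-month replicates 1, 2 and 3. With place on the slide in the model 9 genes were called and with the airway marker score 36. All 179 kept their direction under both, with median sizes 0.991 and 0.969 times as large and median errors 1.5 and 1.35 times as wide. Genes that vary with place or airway signal would seldom be called, so the kept sizes do not decide on either. Ephx4 lost its call in 8 of the 12 fits that left out 1 heart, Tent5b in 7, Aqp8 in 4, Ankrd63 in 3 and Mylpf in 2, whereas Myh7, Casq1, Sds and Csdc2 kept theirs in every setting run.

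**Figure D1:**
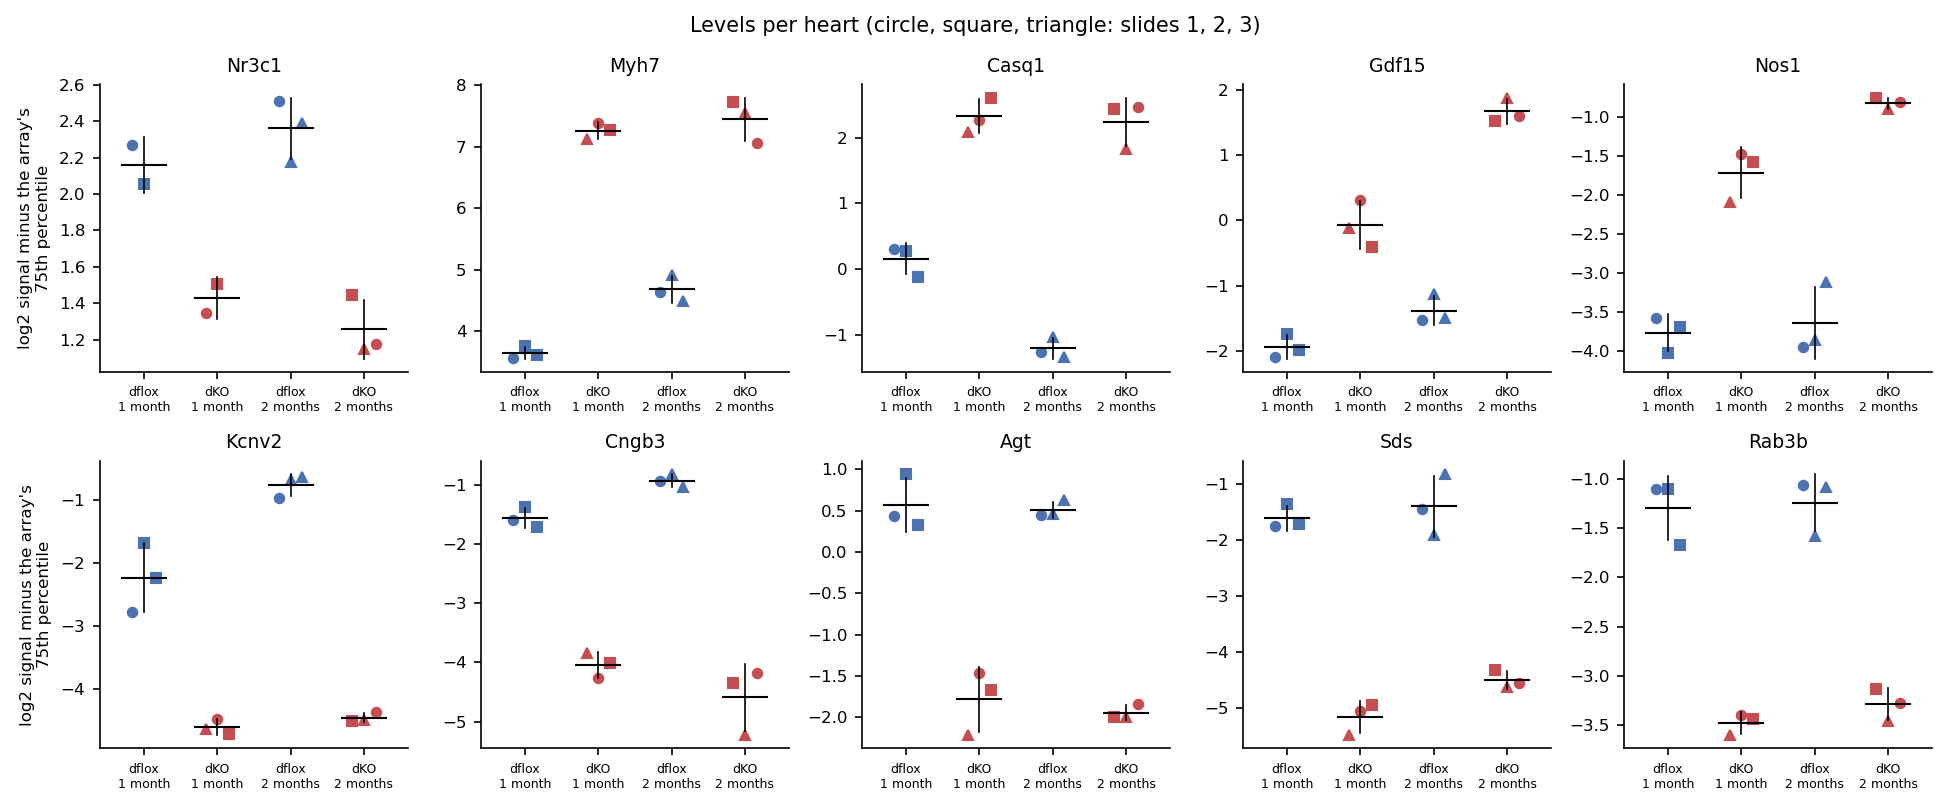
Log2 level of 10 genes in each heart, relative to the array's 75th percentile, in dflox (blue) and cardioGRMRdKO (red) hearts at 1 and 2 months, with the mean as a line and the SD as a bar. Circles, squares and triangles are arrays of slides 1, 2 and 3. Myh7 rose from 3.65 ± 0.098 to 7.26 ± 0.138 between dflox and knockout hearts at 1 month.

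By camera, 12 of 31 gene lists shifted at 1 month, 2 up and 10 down. None of these calls held with an estimated correlation, whose adjusted p is given beside each. Macrophage markers were higher, with 22 of 23 members above 0 and a median of 0.24 (adjusted p = 5.42e-05, and 0.213 with an estimated correlation), although none of the members passed the test alone. Aif1 and Tyrobp stood at 0.38 and 0.33. The fetal and hypertrophic genes split: 5 members rose, Myh7, Mybpc2 (1.16, adjusted p = 0.00476), Cck (1.25, 0.0249), Ankrd1 (0.93, 0.0267) and Nppb (1.47, 0.0464), and the slow troponin gene Tnni1 fell (−1.21, 0.00722). The list's median was −0.04, its mean 0.29 and its camera direction up (adjusted p = 0.0377, and 0.418 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell. Nppb, the gene of B-type natriuretic peptide, lost its call in 8 of the 12 fits without 1 heart. Nppa, the A-type peptide, differed by −0.26, Acta1 by 0.83 and Myh6, the adult α-myosin heavy chain, by −0.48, none of which passed.

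Metabolic and stromal lists were lower at 1 month without single members passing over all genes. Fatty acid uptake and oxidation had 30 of 33 members below 0 and a median of −0.18 (adjusted p = 4.75e-04, and 0.268 with an estimated correlation), and the respiratory chain 40 of 44 and −0.12 (0.00333, and 0.688 with an estimated correlation). The respiratory chain call did not hold with quantile normalization (median −0.02, adjusted p = 0.534), normexp (−0.03, 0.802) or without slide 3 (−0.08, 0.399), nor did that of the fatty acid genes without slide 3 (−0.17, 0.151). Fibroblast markers had a median of −0.19 with 20 of 20 below 0 (adjusted p = 2.86e-04), epicardial and valve markers −0.40 with 18 of 19 (1.41e-04), extracellular matrix genes −0.15 with 31 of 36 (0.00116), smooth muscle and pericyte markers −0.21 with 12 of 15 (0.00116) and atrial markers −0.34 with 16 of 17 (2.86e-04). With an estimated correlation their adjusted p was 0.213, 0.213, 0.268, 0.213 and 0.367. The mean level of the atrial markers was 1.97 in knockout replicate 1, 2.84 and 2.67 in the other knockout hearts and 2.9 in each dflox heart, and without slide 3, which holds that replicate, their median was −0.13 (0.195). Glucocorticoid receptor targets had 24 of 34 members below 0 and a median of −0.24 (adjusted p = 0.00311, and 0.268 with an estimated correlation). None was called over all genes, and adjusted over the list alone 1 rose and 2 fell. Mineralocorticoid receptor targets had 15 of 19 below 0 and a median of −0.32 (0.00945, and 0.213 with an estimated correlation), and juvenile growth genes 18 of 23 and −0.10 (0.0223, and 0.213 with an estimated correlation). The mean of airway markers was 4.39 log2 units lower in the knockout hearts at 1 month. With the airway score in the model the calls of 7 lists did not hold. The medians of the glucocorticoid and mineralocorticoid receptor targets and of the epicardial and valve markers moved to 0.01 (adjusted p = 0.485), −0.07 (0.439) and −0.19 (0.138). Those of extracellular matrix (−0.13, 0.202) and smooth muscle (−0.19, 0.202) stayed about as large, that of juvenile growth genes was −0.16 (0.263) and that of fetal genes 0.00 (0.125). With place in the model the calls of extracellular matrix genes (median −0.11, 0.381) and epicardial and valve markers (−0.21, 0.15) did not hold. With slide as a fixed term 6 calls did not hold: glucocorticoid (median −0.18, adjusted p = 0.0701) and mineralocorticoid receptor targets (−0.29, 0.085), fetal genes (−0.07, 0.0541), fatty acid genes (−0.18, 0.0541), the respiratory chain (−0.11, 0.113) and juvenile growth genes (−0.09, 0.113). The macrophage list kept its call (0.24, 1.33e-05), and within slides 1 and 2 its median was 0.32 and 0.17.

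At 2 months the same question was asked of older hearts. Knockout hearts had 10.9-fold more Casq1, 8.29-fold more Gdf15, 7.05-fold more Nos1 and 6.79-fold more Myh7 RNA than dflox hearts. Kcnv2 was 12.9-fold lower, Cngb3 12.6-fold lower and Agt 5.48-fold lower. Ppp1r1c, an inhibitor of protein phosphatase 1, was well above background on 0 of 3 dflox arrays and rose at least 8.79-fold in the main setting. Over the alternatives its log2 difference ran from 1.15 to 4.52. limma called 422 genes, 201 higher and 221 lower, 187 of them by 2-fold or more.

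The adjusted p of Ppp1r1c (chromosome 2, 79652624 to 79652683) was 1.34e-04. In log2 units, Casq1 stood at 3.45 (SE 0.206, adjusted p = 8.96e-05), Gdf15 at 3.05 (SE 0.194, adjusted p = 8.96e-05), Nos1 at 2.82 (SE 0.234, adjusted p = 3.63e-04) and Myh7 at 2.76 (SE 0.178, adjusted p = 8.96e-05), the last from 4.68 ± 0.219 to 7.44 ± 0.352. Rprm, a p53-induced gene, rose by 2.73 (adjusted p = 0.00136) and Fgf6 by 2.92 (4.62e-04; 1 of 3 dflox arrays above background). Ephx4, Kctd16 and the carotenoid-cleaving oxygenase gene Bco2 rose at least 6.37-fold, 3.74-fold and 2.44-fold (adjusted p = 0.00265, 0.0106 and 0.0258). Kcnv2 fell by 3.69 (SE 0.229, adjusted p = 8.96e-05; chromosome 19, 27036941 to 27037000), Cngb3 by 3.65 (SE 0.242, adjusted p = 9.34e-05), Sds by 3.11 (SE 0.256, adjusted p = 3.63e-04) and Agt by 2.45 (SE 0.205, adjusted p = 3.63e-04; chromosome 8, 123143932 to 123143991). Acsm5 fell 8.37-fold (adjusted p = 0.00264), Lrat by 2.41 (0.0153; 1 of 3 knockout arrays above background) and Vwc2, a secreted inhibitor of BMP signals, by 2.63 (0.00478). Klk1b26, a kallikrein gene, and Catsperb, which encodes a subunit of the sperm calcium channel, fell at least 3.9-fold and 2.35-fold (0.0159 and 0.00926). Acta1, the skeletal α-actin, rose by 1.83 (SE 0.329, adjusted p = 0.0178). Nppb stood at 0.70 (0.273), Nppa at −0.01 (0.987) and Myh6 at −0.11 (0.797). The largest changes were named on the condition that the groups did not overlap. Over all genes, 17.7% had groups that did not overlap, where chance gives 10%.

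All 421 called genes with a value kept their sign within slide 1 and all 420 within slide 3. Here too the hearts are those that made the calls, 1 or 2 per group and slide, so this decides nothing. With slide as a fixed term 292 genes were called. The count fell to 240 and 249 without dflox 2-month replicates 2 and 3, to 268 without knockout 2-month replicate 1, and to 111 without the 4 arrays of slide 3, which leaves 1 dflox heart that is assumed to vary like the other groups. Bco2, Klk1b26 and Lrat lost their calls in 3 of the 12 fits without 1 heart and Acta1 in 4.

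By camera, 5 lists shifted at 2 months, and none with an estimated correlation. The respiratory chain had 42 of 44 members below 0 and a median of −0.31 (adjusted p = 4.67e-06, and 0.822 with an estimated correlation), with Ndufv2 at −0.41, and fatty acid uptake and oxidation had 29 of 33 and −0.35 (6.46e-04, and 0.658 with an estimated correlation). No member of either list passed over all genes. Adjusted over the list alone, 10 fatty acid genes fell. Hadh stood at −0.48 and Eci1 at −0.68. Mitotic cell cycle genes were higher, with 31 of 43 above 0 and a median of 0.22 (1.52e-05, and 0.822 with an estimated correlation), and Mcm2 (0.92, adjusted p = 0.00913) and Ube2c (1.16, 0.0486) rose. Macrophage markers were higher again, with 21 of 23 above 0 and a median of 0.19 (1.77e-05, and 0.474 with an estimated correlation). Among fetal and hypertrophic genes 6 rose, including Mybpc2 (1.67, adjusted p = 4.00e-04), Cck (1.60, 0.00417), Uchl1 (0.93, 0.0154) and Rcan1 (0.81, 0.0197), and Tnni1 fell (−0.94, 0.016). That list had a median of 0.18 (adjusted p = 3.09e-04, and 0.474 with an estimated correlation), and over the list alone 7 rose and 2 fell. Within slides 1 and 3 the medians were −0.55 and −0.26 for the respiratory chain, −0.37 and −0.37 for fatty acid genes, 0.30 and 0.29 for mitotic genes, 0.39 and 0.18 for macrophage markers and 0.36 and 0.11 for fetal genes. With slide as a fixed term the adjusted p of these lists was 1.60e-06, 1.01e-04, 1.56e-06, 1.15e-04 and 8.68e-04. Quantile normalization left 3 of the lists called, all of them higher. Over the alternatives the median ran from −0.36 to −0.11 for the respiratory chain and from −0.41 to −0.15 for fatty acid genes.

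Single members of other lists also passed at 2 months. Kcne1, a potassium channel β subunit gene, fell by 1.17 (adjusted p = 0.016). Camk2b rose by 0.66 and 0.59 at the 2 ages (0.0169 and 0.016), and at 2 months Cacna2d1 fell by 0.77 (0.0292) and Slc8a1, the sodium-calcium exchanger gene, by 0.64 (0.0371). Pfkfb1, a regulator of glycolysis, fell by 1.60 (0.00912) and 1.79 (0.00297). Cdkn1a, which encodes the cell cycle inhibitor p21 and belongs to the glucocorticoid receptor target list, rose by 1.56 at 2 months (0.00282), opposite to Mt1, a metallothionein gene, at −1.03 (0.0465). Ucp2 rose by 1.42 (0.0108) and Acta2 by 0.91 (0.0225).

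**Figure D2:**
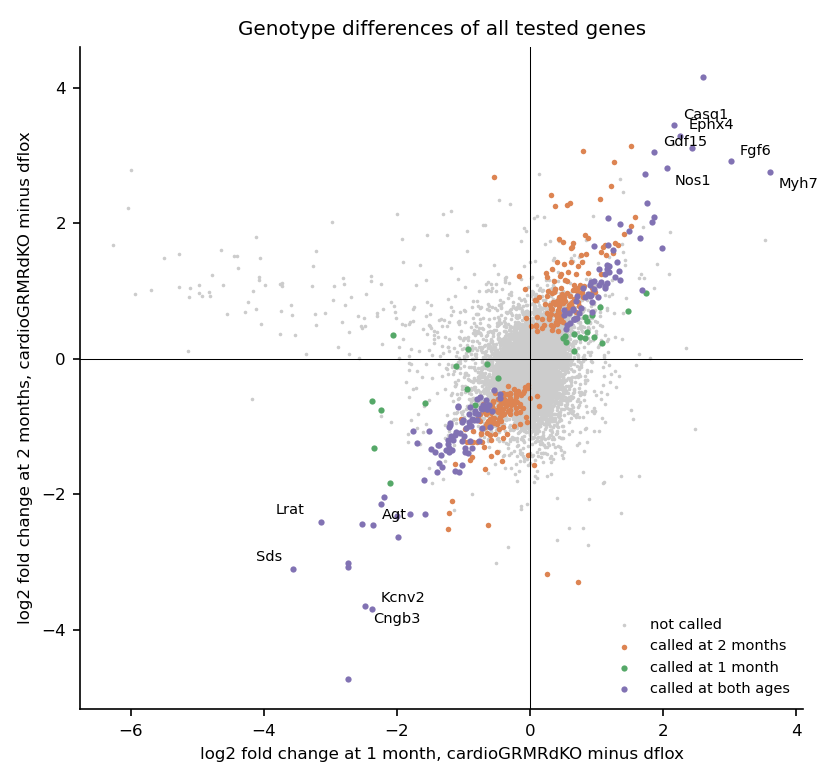
Log2 difference between cardioGRMRdKO and dflox hearts at 1 month (horizontal) and at 2 months (vertical) for each gene. Purple genes were called at both ages, green at 1 month, orange at 2 months and grey at neither; 151 genes were called in the same direction at both ages.

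Most of what passed at one age pointed the same way at the other. Of the 179 genes called at 1 month, 177 had the same sign at 2 months, and 413 of the 422 called at 2 months had the same sign at 1 month. In total 151 genes passed at both ages in the same direction, 64 higher and 87 lower, where 0.881 and 1.2 would be expected if the calls were independent, and none passed in opposite directions. Both comparisons take each gene's variance from the same fit, so their calls are not fully independent and these expected counts may be too low. Myh7, Casq1, Gdf15, Nos1, Fgf6 and Ephx4 were among the shared rises and Sds, Lrat, Acsm5, Cngb3, Kcnv2, Agt and Csdc2 among the shared falls. Ppp1r1c at 1 month rose at least 1.61-fold (adjusted p = 0.00252; 2 of 3 knockout arrays above background) and Catsperb stood at 0.72 (0.853). Without dflox 1-month replicates 1, 2 and 3 the shared count was 77, 80 and 92, and without knockout 1-month replicates 1, 2 and 3 it was 76, 78 and 73. It was 93 with slide as a fixed term, 9 with place, 35 with the airway score and 31 without slide 3. Across all genes, which are not independent replicates, the genotype differences at the 2 ages had a Pearson correlation of 0.182 and a Spearman correlation of 0.314. The Pearson value was −0.03 without knockout 2-month replicate 2 and −0.10 without slide 3.

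Averaged over both ages, with 6 hearts against 6, 821 genes passed, 411 higher and 410 lower, and 176 differed by 2-fold or more. Myh7 rose 9.1-fold (3.19, SE 0.126, adjusted p = 2.72e-06). Of genes not named so far, the largest rises were those of Brinp1 (1.99, adjusted p = 0.0243), Tbx15 (1.88, 0.0107), Morn4 (1.71, SE 0.11, 2.39e-05) and Smcr8 (1.66, 0.00659), with Tbx15 well above background on 2 of 6 dflox arrays, Smcr8 on 3 and Brinp1 on 4. Dgki, on 0 of 6, rose at least 2.63-fold at 2 months (0.0362). The largest falls were those of the cadherin gene Cdh22 (−2.40, 0.00982), Rab3b, which encodes a GTPase of secretory vesicles (−2.12, SE 0.133, 2.14e-05), Phyhd1 (−2.04, SE 0.155, 6.16e-05), Rasl10a (−1.93, 2.30e-04) and Myot, which encodes the Z-disc protein myotilin (−1.75, 3.41e-04). A lack of overlap between the groups was a condition for naming these genes. Brinp1 lost its call in 7 of the 12 fits without 1 heart. Nppb rose by 1.08 (0.0127), Acta1 by 1.33 (0.00913), and Ryr2, the calcium release channel of the sarcoplasmic reticulum, fell by 0.38 (SE 0.0715, adjusted p = 0.0126) with no overlap between the genotypes.

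In the averaged comparison, of 34 glucocorticoid receptor targets, 25 were below 0, with a median of −0.20 that did not pass by camera (adjusted p = 0.0536, and 0.655 with an estimated correlation) and passed by fry (adjusted p = 0.0491). Over the 12 alternatives run for lists the median ran from −0.27 to −0.08, and the list passed in 4 of them, fry included. Over all genes 1 rose and 4 fell, and over the list alone 1 rose and 6 fell. Cdkn1a rose by 1.20 (adjusted p = 8.25e-04), and Mt1 (−1.0, 0.00567), Cebpb (−0.65, 0.00726), Ptgds, a prostaglandin D synthase (−1.30, 0.0153), and Klf9 (−0.48, 0.0358) fell. Klf15 stood at −0.75 (0.076), Fkbp5 at −0.56 (0.142), Per1 at −0.86 (0.235), Tsc22d3 at −0.13 (0.642) and Sgk1 at 0.08 (0.853). Mineralocorticoid receptor targets had a median of −0.16 (adjusted p = 0.366), and no member passed.

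By camera 6 lists shifted in the averaged comparison, and none with an estimated correlation. Macrophage markers were higher with 22 of 23 above 0 and a median of 0.22 (adjusted p = 6.35e-07, and 0.424 with an estimated correlation). Fcgr1 rose by 0.35 (0.0433), and over the list alone 2 rose. The respiratory chain had 43 of 44 members below 0 and a median of −0.20 (3.68e-06, and 0.677 with an estimated correlation), and Ndufv2 fell by 0.37 (0.0336). With quantile normalization this list had a median of −0.05 (0.14). Fatty acid uptake and oxidation had 29 of 33 below 0 and a median of −0.27 (6.92e-05, and 0.562 with an estimated correlation). Acaa2 (−0.41, 0.0284) and Hadh (−0.36, 0.0341) fell, and over the list alone 17 fell and 1 rose. Atrial markers were lower (median −0.23, 0.022, and 0.687 with an estimated correlation), with Kcnj3 at −0.72 (0.0103), and did not pass without slide 3 (−0.14, 0.0621), with the airway score (−0.22, 0.0781) or with normexp (−0.13, 0.0563). Mitotic genes had a median of 0.09 (0.00386, and 0.724 with an estimated correlation), with Mcm2 and Ube2c higher, and did not pass without slide 3 (0.06, 0.224). Fetal genes had a median of 0.03 and a mean of 0.35 (0.00427, and 0.562 with an estimated correlation), with 8 members higher and 1 lower. Cardiac ion channel genes did not pass as a list by camera (median −0.20, 0.0536) and passed by fry (0.00936), as did juvenile growth genes (0.0171) and fibroblast (0.0323) and smooth muscle markers (0.0491). Of the ion channel genes, over all genes 1 member rose and 4 fell, Kcnj3, Kcnj12 (−0.56, 0.0112) and Kcne1 (−0.79, 0.0126) among the falls. Skeletal muscle markers went both ways, with Casq1 (2.81, 1.44e-05) and Mylpf (1.36, 0.00232) higher and Pvalb (−1.53, 0.0243), Myl1 (−0.89, 0.0357) and Tnni2 (−0.68, 0.0229) lower.

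The averaged call count was 973 with slide as a fixed term. It was 530 and 507 without knockout 1-month replicates 2 and 3, 257 with place in the model and 234 without slide 3.

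**Figure D3:**
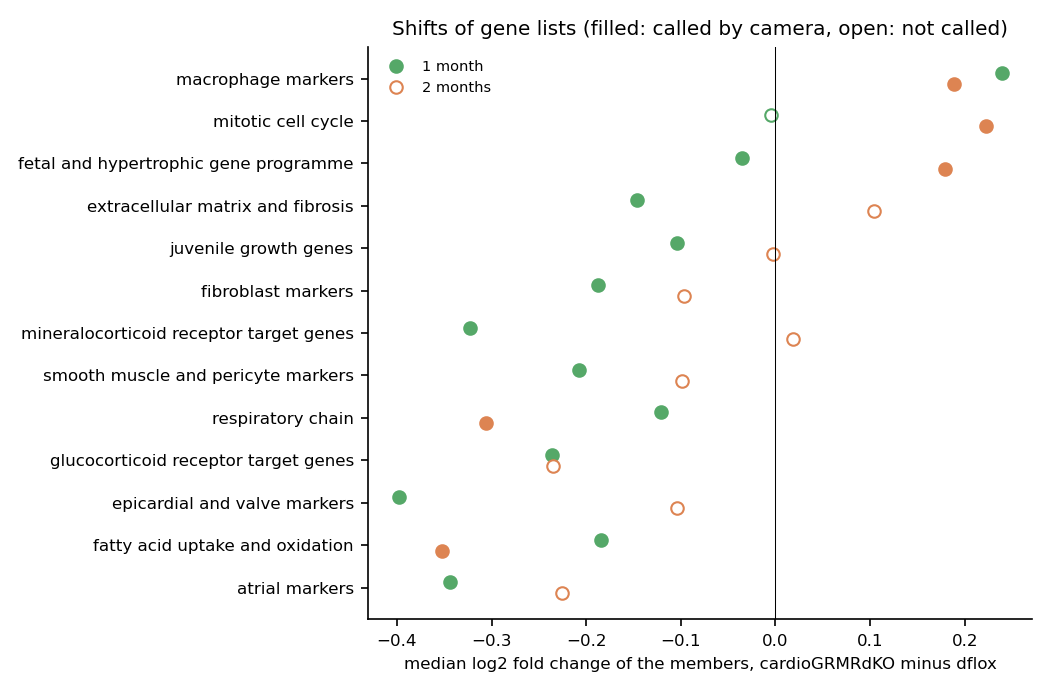
Median log2 difference between cardioGRMRdKO and dflox hearts over the members of each gene list called at 1 month (green) or 2 months (orange). Filled points were called by camera with the preset correlation. Macrophage markers were called at both ages, with medians of 0.24 and 0.19, but not with an estimated correlation (adjusted p = 0.213 and 0.474).

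Whether the genotype effect differed between the ages was tested as an interaction. limma called 0 of 18258 genes, with 644 at an unadjusted p under 0.05 and a lowest adjusted p of 0.934. Genes that passed at one age alone, such as Catsperb or Acta1, are therefore not shown to differ between the ages. Without slide 3, 138 genes were called, and with place in the model 1. By camera 15 lists differed, 14 of them with a higher genotype difference at 2 months, led by extracellular matrix genes (median difference 0.17, adjusted p = 1.09e-06) and mitotic genes (0.25, 3.26e-06). None of the 15 was called with an estimated correlation or by fry, and 8 of the 15 did not hold with slide as a fixed term and 10 with the airway score.

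Between 1 and 2 months, genes of the matrix and of dividing cells became lower in dflox hearts, the mitotic list only with the preset correlation (adjusted p = 0.166 with an estimated one). The elastin gene Eln fell 3.97-fold, the collagen gene Col26a1 3.98-fold, and the mitotic genes Nek2, Birc5, Plk1 and Cdc20 3.59-fold, 3.31-fold, 3.12-fold and 2.93-fold. Aqp8 rose 4.46-fold and Myh7 rose 2.04-fold, a log2 change of 1.03 (SE 0.178, adjusted p = 0.0396). limma called 101 genes, 56 higher and 45 lower at 2 months.

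The further rises were those of the glutathione transferase genes Gsta2 (1.90, adjusted p = 0.0203) and Gsta1 (1.62, 0.0115), the chemokine gene Cxcl14 (1.63, 0.0184), Prune2 (1.62, 0.0139), Armc2 (1.55, 0.0142; 2 of 3 arrays above background at 1 month), the MHC class II genes H2-Aa (1.5, 0.0453) and H2-Ab1 (1.48, 0.0387), and Gng7, which rose at least 1.87-fold (0.0115). Aqp8 stood at 2.16 (SE 0.34, adjusted p = 0.0265). The falls were Col26a1 (−1.99, SE 0.239, adjusted p = 0.0115), Eln (−1.99, SE 0.311, adjusted p = 0.026), Nek2 (−1.85, 0.0203), Birc5 (−1.73, 0.0382), Cdca3 (−1.65, 0.0472), Plk1 (−1.64, 0.0448), Pask (−1.61, 0.0246), Cdc20 (−1.55, 0.0268), C1qtnf6 (−1.47, 0.0246) and Cks2 (−1.38, 0.0478). A lack of overlap was a condition for naming these genes, and it held in 20.2% of all genes, where chance gives 10%.

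Extracellular matrix genes were lower at 2 months in dflox hearts in 36 of 36 members, with a median of −0.58 (camera adjusted p = 7.70e-24), and 7 passed over all genes and 24 over the list alone, among them Col1a1 (−1.23, adjusted p = 0.0131), Loxl2 (−1.17, 0.0115), Col5a1 (−0.91, 0.0115) and Fbn1 (−0.92, 0.0184). Fibroblast markers were lower in 20 of 20 (median −0.36, 1.04e-13), with Mfap5 at −1.21 and Mfap4 at −1.04 (0.0246 each), and juvenile growth genes in 19 of 23 (median −0.25, 2.26e-06), with Igf2 at −0.91 (0.0184). These 3 calls held with an estimated correlation (adjusted p = 0.00488 for each). Mitotic genes were lower in 42 of 43, with a median of −1.17 (2.92e-33, and 0.166 with an estimated correlation), and 4 passed over all genes and 38 over the list alone. Of the other 10 lists called by camera alone, fatty acid uptake and oxidation was higher (median 0.21, 0.00371, and 0.426 with an estimated correlation). The lower ones were smooth muscle and pericyte (−0.15, 0.00114), interferon-induced (−0.17, 0.00168), epicardial and valve (−0.22, 0.00397), immediate early (−0.29, 0.00801), endothelial (−0.14, 0.0228), mineralocorticoid receptor target (−0.18, 0.0244), glucocorticoid receptor target (−0.15, 0.0464), macrophage (−0.15, 0.0464) and adipocyte genes (−0.43, 0.0464), with an adjusted p of 0.204, 0.204, 0.364, 0.634, 0.204, 0.204, 0.574, 0.623 and 0.832 with an estimated correlation. Of these 10 lists, fatty acid and smooth muscle genes kept their calls with slide as a fixed term, place, the airway score, quantile normalization and normexp and without slide 3. Airway and cartilage markers fell with age as well (mean −2.60, camera adjusted p = 3.21e-05, and −1.04, 1.14e-05, with an unadjusted p of 0.25 and 0.0684 with an estimated correlation). With the airway score the matrix (−0.585, 4.32e-20) and fibroblast lists (−0.40, 3.94e-13) kept their calls, whereas the epicardial and valve (−0.02, 0.206), macrophage, adipocyte and both receptor target lists did not.

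Only slide 1 held dflox hearts of both ages, and there all 101 genes kept their sign. This compares 1 heart with 1 among those that made the calls, so it decides nothing. With slide as a fixed term 10 genes were called, while the matrix, fibroblast, mitotic and juvenile growth lists kept their calls (adjusted p = 5.45e-20, 1.72e-11, 1.01e-31 and 6.84e-05). The glucocorticoid (0.408) and mineralocorticoid receptor target (0.234), interferon-induced (0.0607), endothelial (0.32), macrophage (0.347), epicardial and valve (0.239) and adipocyte lists (0.346, median turned to 0.28) did not. The count was 3, 18, 66, 11 and 17 without dflox 1-month replicates 1 and 3 and dflox 2-month replicates 1, 2 and 3, and 51 without knockout 1-month replicate 3. It was 28 with place, 6 with the airway score and 14 without slide 3. The split of 56 higher and 45 lower turned to 41 and 75 with normexp correction and to 64 and 85 with quantile normalization. Of the 20 genes named for this comparison, Gng7 kept its call in every fit without 1 heart.

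In knockout hearts 69 genes differed between the ages, 35 higher and 34 lower. Kcne1 fell by 1.92 (adjusted p = 0.00749), Loxl2 by 1.17 (0.00749), Col1a1 by 1.08 (0.0274), Col5a1 by 0.74 (0.0274) and Igf2 by 0.79 (0.0355), and Gsta1 (1.32, 0.0274), Rcan1 (0.93, 0.0355) and the heat shock gene Hsph1 (0.76, 0.0274) rose. Mitotic genes were lower in 42 of 43 (median −0.89, adjusted p = 1.65e-18, and 0.294 with an estimated correlation), matrix genes in 30 of 36 (−0.42, 2.29e-09, and 0.101 with an estimated correlation) and fibroblast markers in 16 of 20 (−0.23, 1.62e-05, and 0.101 with an estimated correlation). Of the other lists called by camera, fetal and hypertrophic (0.18, 0.00348), heat shock and unfolded protein (0.16, 0.00461), lymphocyte and thymus (0.33, 0.0122), fatty acid (0.09, 0.0378) and prostaglandin genes (0.11, 0.043) were higher and interferon-induced (−0.26, 0.00361) and respiratory chain genes (−0.15, 0.0198) lower, with an adjusted p of 0.294, 0.294, 0.347, 0.549, 0.37, 0.294 and 0.725 with an estimated correlation. The respiratory chain call did not hold with quantile normalization (−0.03, 0.647), normexp (−0.06, 0.198), the airway score (−0.09, 0.233) or place (−0.07, 0.255), the prostaglandin call with slide as a fixed term (0.11, 0.0587), the airway score (0.09, 0.234) or place (0.08, 0.0953), and the lymphocyte call with the airway score (0.35, 0.132) or place (0.24, 0.0656). Without slide 3 the fetal, heat shock, fatty acid, prostaglandin and interferon lists did not pass (adjusted p = 0.128, 0.0902, 0.14, 0.122 and 0.122). All 69 genes kept their sign within each of the 3 slides, which compares 1 heart with 1 among those that made the calls and decides nothing. With slide as a fixed term 46 genes were called. The count was 44 and 15 without dflox 1-month replicates 1 and 3, 9 and 4 without knockout 1-month replicates 1 and 3, 35, 39 and 41 without dflox 2-month replicates 1, 2 and 3, and 19, 10 and 23 without knockout 2-month replicates 1, 2 and 3. It was 16 with place and 15 with the airway score.

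Markers of tissue next to the heart varied between hearts. The airway epithelium list averaged 1.31 ± 0.69 in dflox and −3.08 ± 0.729 in knockout hearts at 1 month (log2, SD, n = 3 each), and −1.28 ± 2.91 and −0.28 ± 3.19 at 2 months, where dflox replicate 3 (1.94) and knockout replicates 1 (1.51) and 3 (1.60) were high. Scgb1a1 and Scgb3a1, secretoglobin genes of airway cells, stood at 4.36 and 4.09 in dflox and −0.47 and −0.88 in knockout hearts at 1 month, and neither passed the test (adjusted p = 0.41 and 0.364). The means of cartilage markers differed by −1.49 at 1 month and 0.13 at 2 months, those of alveolar markers by −1.15 and 0.06, and those of neutrophil markers by 0.26 and 0.79. The alveolar median at 1 month was −9.08e-04, so that list's mean does not stand for a fall across its members. By camera the airway and cartilage lists were lower in knockout hearts at 1 month (adjusted p = 6.96e-13 and 3.31e-10, with an unadjusted p of 0.0671 and 0.0207 with an estimated correlation). The alveolar and neutrophil lists were not called (adjusted p = 0.835 and 0.447). Of the 16 airway genes measured, 12 were well above background on all arrays, and 0 belonged to another list. Adipocyte markers averaged −0.15 in knockout replicate 1 at 1 month, 0.30 in dflox replicate 2 and 0.23 in knockout replicate 2 at 2 months, all on slide 3, and between 1.19 and 2.47 in the other hearts.

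**Figure D4:**
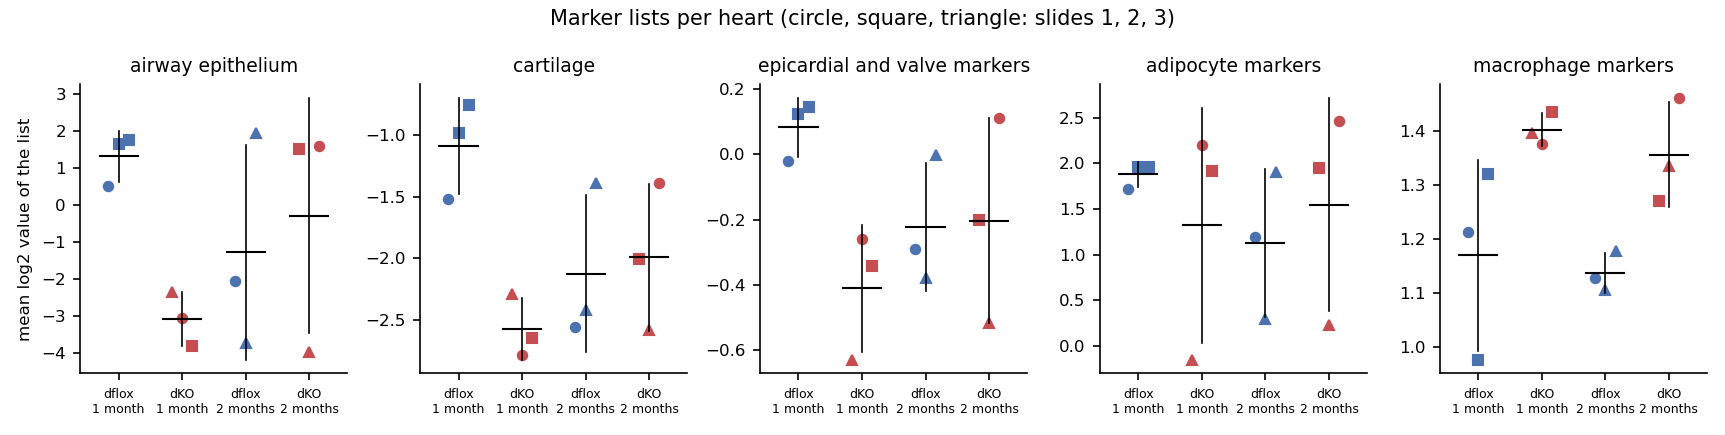
Mean log2 level of the airway epithelium, cartilage, epicardial and valve, adipocyte and macrophage marker lists in each heart, relative to the array's 75th percentile, by genotype and age, with group mean and SD. Airway markers averaged 1.31 in dflox and −3.08 in knockout hearts at 1 month.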

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

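Of the tests in this part, those that set the 1-month genes against place and airway signal, those that fit place or the airway score over all hearts, and those that set the macrophage rise against the share of cardiomyocyte RNA, were chosen after the result was seen, as were the alternatives with place or the airway score in the model.

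For 15 gene lists the genotype shift differed between the ages by camera's test of the interaction, with the preset correlation. None of the 15 was called with an estimated correlation, where adjusted p ran from 0.144 to 0.703, or by fry. The median log2 difference, 2 months minus 1 month, was 0.166 for extracellular matrix and fibrosis (adjusted p = 1.09e-06), 0.252 for mitotic cell cycle (3.26e-06), 0.178 for epicardial and valve markers (2.85e-04) and 0.151 for fibroblast markers (4.45e-04). It was 0.893 for adipocyte markers (0.0024), but −0.113 (0.925) with slide as a fixed term and −0.898 (0.196) with the airway score. Their mean level was −0.15, 0.30 and 0.23 in 3 hearts of slide 3 and 1.19 to 2.47 in all others. The median difference was 0.168 for mineralocorticoid receptor targets (0.00381), 0.183 for smooth muscle and pericyte markers (0.00381), 0.112 for juvenile growth genes (0.00391) and 0.149 for prostaglandin and arachidonate metabolism (0.00705). It was −0.175 for the respiratory chain (0.00722), the 1 list that was lower, 0.236 for nerve and Schwann cell markers (0.0113), 0.209 for immediate early genes (0.0137), 0.22 for atrial markers (0.0198), 0.2 for the fetal and hypertrophic programme (0.0235) and 0.0489 for heat shock and the unfolded protein response (0.0235). With slide as a fixed term 8 of the 15 did not hold: adipocyte, mineralocorticoid receptor target (0.0595), smooth muscle (0.0665), fetal (0.124), heat shock (0.155), nerve (0.163), prostaglandin (0.347) and atrial lists (0.777, median 0.00819). With the airway score 10 did not hold: adipocyte, immediate early and juvenile growth (0.149 each), mineralocorticoid receptor target, atrial, and epicardial and valve (0.269 each), prostaglandin (0.276), smooth muscle and nerve (0.454 each) and respiratory chain lists (0.485). With place in the model 5 did not hold: fetal (0.054), prostaglandin and adipocyte (0.0627 each), nerve (0.436) and respiratory chain lists (−0.0516, 0.843). Without slide 3 it was the fibroblast (0.151), juvenile growth (0.289), fetal (0.374), atrial (0.454), prostaglandin (0.605) and heat shock lists (0.946), with quantile normalization the respiratory chain (−0.0546, 0.123) and with normexp the fetal (0.102) and heat shock lists (0.113). With 15 lists in the real split and at most 15 in the others (median 7), 2 of 100 splits of the hearts gave as many, a share under 0.05. This cannot exclude chance for their number, since another split gave 15 as well and slide was left aside. The splits do not hold slide fixed, and with slide as a fixed term 9 lists were called.

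Airway tissue left on the hearts may account for part of these age differences, since the airway score's own genotype difference changed by 5.39 log2 units between the ages. From its slope within groups, the score predicts 75.1% (95% interval 14.2 to 136) of the change of 0.513 in the mean of the epicardial and valve markers. For extracellular matrix genes (64.5%, −18.8 to 148), fibroblast markers (−41.7%, −278 to 195) and mitotic genes (−46.4%, −287 to 194) the intervals are too wide to decide, and airway tissue and an age-dependent effect of genotype cannot be told apart. With the score in the model the epicardial and valve list lost its call (median 0.05, adjusted p = 0.269), whereas mitotic (0.40, 8.26e-07), matrix (0.10, 0.0192) and fibroblast genes (0.05, 0.0202) were still called. An effect of genotype that changes with age stays open for all 4 lists and was not tested apart from these values.

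At 1 month genotype and place on the slide coincide and airway markers were 4.39 log2 units lower in knockout hearts, so either might have made the 179 calls. With place in the model, its effect taken from the 2-month hearts, the median call keeps 99.1% of its size (97.4% to 101% without any 1 of these hearts). This decides nothing, since a gene moved by place would also vary among the 2-month hearts and would seldom be called. Only 9 genes stay called, with errors 1.5 times as wide. An effect of place on the 1-month arrays alone cannot be told apart from genotype. Within the outer and inner places 97.2% and 98.9% of the calls had the same sign at 2 months, but each comparison has 1 array on a side and decides nothing. Of the calls, 98.9% kept their sign at 2 months, where the airway score differed the other way by only 0.997 (SD 2.91 and 3.19). This does not decide on airway tissue, since airway genes varied too widely among the 2-month hearts to be called. Scgb1a1, for example, stood at −4.82 at 1 month (SE 1.87, adjusted p = 0.41). Place, airway tissue and a genotype effect present at both ages all stay open for these calls, with Cre itself not separated from its action on the receptor genes.

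The macrophage list was higher in knockout hearts at both ages by camera with the preset correlation, but not with an estimated one (adjusted p = 0.213 at 1 month, 0.474 at 2 months and 0.424 averaged). A lower share of cardiomyocyte RNA would raise the markers of every other cell type alike, yet the macrophage mean rose by 0.226 while the endothelial, fibroblast and smooth muscle means stood at −0.101, −0.167 and −0.157, and the contrast of 0.368 had an exact permutation p of 0.005, the smallest that the 400 arrangements can give. With place in the model the rise at 2 months was 0.248 (95% interval 0.0344 to 0.462). This argues against place as its whole cause at that age. The averaged rise was 0.283 (0.0815 to 0.484). That average does not decide on 1 month, where place and genotype coincide and the effect of place is taken from the 2-month hearts. The medians of 0.199 within inner and 0.29 within outer places at 2 months have 1 array on a side and decide nothing. Airway tissue is argued against as the whole cause by an averaged rise of 0.238 (0.0724 to 0.403) with the airway score in the model, although the intervals at 1 month (0.263, −0.0162 to 0.541) and at 2 months (0.213, −0.00281 to 0.428) include 0, and it stays open as part of the cause, since its slope within groups predicts −13% (−91.1 to 65.1) of the rise of 0.232 at 1 month. More macrophages, or higher expression in the same number, may underlie the rise, and whole-heart RNA does not separate these.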

How the results depend on the processing

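The alternatives with place, the airway score and without slide 3 were chosen after the data had been seen; the others were fixed before. Where a count moved, the cause was not tested unless the setting's construction shows it, as where genes or arrays are fewer. Genes called were 179 at 1 month, 422 at 2 months, 821 averaged, 0 for the interaction, 101 and 69 with age in dflox and knockout hearts, and 151 shared between the ages.

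Counts stayed within 1.5 times of these with normexp, the other scalings, the series matrix values, every probe alone, the mean of probes and slide as a random term. With no filter on dim probes, which tests more and noisier probes, they were 91, 243, 518, 0, 17, 13 and 76. With only probes well above background on all 12 arrays, 175 genes changed with age in dflox hearts, and with a trended robust variance 213. Fitting only the 6 arrays compared gave 97 genes at 2 months and 0 with age in either genotype, with fewer arrays to estimate the variance. Array weights gave 803 at 1 month, 1434 averaged, 265 and 209 with age and 292 shared. Slide as a fixed term gave 10 with age in dflox hearts, where slide and age overlap, and 93 shared.

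Place in the model gave 9 at 1 month, 257 averaged, 1 for the interaction, 28 and 16 with age and 9 shared. The airway score gave 36, 6 and 15 with age, and 35 shared. Without slide 3, which leaves a lone 2-month dflox heart assumed to vary like the other groups, 111 genes were called at 2 months, 234 averaged, 138 for the interaction, 14 with age in dflox hearts and 31 shared, and the correlation across genes reversed to −0.09678.

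Replicate numbers did not pair the hearts: deviations of hearts with the same number correlated at a median of −0.0103 over 18 pairs, and 3 of 12 arrays correlated best with their own number. With the replicate block 136, 326, 691, 0, 75, 31 and 117 genes were called. Leaving out 1 heart gave 82 to 230 genes at 1 month, 240 to 388 at 2 months, 507 to 786 averaged, 0 to 0 for the interaction, 3 to 147 and 4 to 62 with age, 73 to 168 shared, and a correlation from −0.02853 (reversed, without knockout 2-month replicate 2) to 0.3242, with a jackknife SE of 0.365.

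Lists called were 12, 5, 6, 15, 14 and 10 in the same order of comparisons. An estimated correlation left 0, 0, 0, 0, 3 and 0, and fry gave 1, 4, 10, 0, 4 and 3. Quantile normalization gave 3 at 2 months and 9 with age in dflox hearts. Slide as a fixed term gave 6, 8 and 9 lists at 1 month, at 2 months and for the interaction and 8 with age in dflox hearts. Place gave 11 averaged. The airway score gave 7 at 1 month and 5 for the interaction, and the omission of slide 3 gave 9 for the interaction.

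A list counts as reversed where it was called in either setting and its camera direction turned, and a gene where its sign did. The medians of such lists were, with slide as a fixed term, adipocyte markers for the interaction (−0.113) and with age in dflox hearts (0.276). With the airway score they were 0.869 at 1 month, −0.898 for the interaction and 0.246 with age in dflox hearts, and nerve and Schwann cell markers −0.126 for the interaction. Without slide 3, heat shock genes were −0.0403 and atrial markers −0.0932 for the interaction. Medians alone also turned, as that of glucocorticoid receptor targets at 1 month with the airway score (0.0105). Of 110 values of named genes per setting, none reversed, but values not called in any setting turned sign, such as Nr3c2 at 2 months (−1.065 to 0.4163), Sgk1 at 1 month (−0.2703 to 0.3052) and Myh6 at 2 months (−0.316 to 0.2059). Calls were lost most often without slide 3 (41), with place (39), with the airway score (31), with slide as a fixed term (24) and with no filter (22), and in 166 of 1320 values that left out 1 heart. For 26 gene and setting combinations no value was left. Signal over background limits genes given as at least N-fold, and that bound belongs to the main setting. Over the alternatives the log2 difference nearest to 0 was, at 1 month, 0.590 for Fgf6, −0.814 for Acsm5 and −0.300 for Ankrd63. At 2 months it was 1.04 for Ephx4, 0.539 for Bco2, 0.589 for Kctd16, −0.326 for Klk1b26 and −0.450 for Catsperb. For Gng7 with age in dflox hearts it was 0.1975.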

Other observations

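The split counts and list values here follow tests fixed before the data were examined, and the counts of other probes per gene were added after the results had been seen.

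Genes of the prostaglandin and arachidonate list moved in both directions in the averaged genotype comparison, although the list as a whole did not pass (median 0.01, adjusted p = 0.72). Ptgfr, which encodes the prostaglandin F receptor, fell by 1.13 (adjusted p = 0.00911) and the phospholipase gene Pla2g12a by 0.43 (0.0102), while the lipoxygenase gene Alox5 rose by 0.87 (0.0118). Tlr2, a receptor of innate immunity, rose by 0.41 (0.0134), while the inflammation and chemokine list stayed near 0 (median −0.04, 0.482). Jph1, a junctophilin gene, fell by 0.70 (0.0278), as did the glutathione transferase gene Gstm2 (−0.52, 0.0112) and the smooth muscle gene Lmod1 (−0.37, 0.0478), and Hsph1 rose by 0.35 (0.0302).

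Several lists did not pass by camera in the averaged comparison. Adjusted p was 0.178 for adult contractile genes (median −0.13), 0.43 for clock genes (−0.11), 0.676 for interferon-induced genes (−0.01), 0.471 for oxidative stress genes (0.02), 0.178 for erythroid markers (0.31), 0.217 for lymphocyte and thymus markers (0.04), 0.352 for glucose uptake and glycolysis (−0.05), 0.92 for calcium handling (−0.05), 0.0874 for atrophy and proteolysis (−0.18) and 0.178 for endothelial markers (−0.11). By fry the atrophy list (adjusted p = 0.0171) and the endothelial list (0.0275) were lower.

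Other probes of called genes mostly pointed the same way. At 1 month 63 of the 179 called genes had other probes that passed the filter, and 74 of those 82 probes had the same sign. At 2 months it was 194 of 213 probes of 151 genes, and averaged over the ages 341 of 369 probes of 274 genes. In 8, 19 and 26 genes a probe pointed the opposite way.

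Other splits of the hearts into groups of the same sizes were counted. The 6 hearts of an age or a genotype give 10 splits, too few for a share under 0.05. At 1 month the real split gave 179 genes and the highest other 0, as against 101 and 0 for age in dflox hearts and 69 and 0 for age in knockout hearts. At 2 months the real split gave 422 genes and another 1273, and this other split parts the slide 3 hearts from the rest, which points to a structure of the samples. With slide as a fixed term 292 genes were called. For lists the real and highest other counts were 12 and 13 at 1 month, 5 and 12 at 2 months, 14 and 11 for age in dflox hearts and 10 and 14 for age in knockout hearts, with 2, 5, 1 and 4 of 10 splits as large. The median count of the other splits was 10, 4, 7 and 7 lists.

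Of splits within both ages, 100 were examined per result. For the averaged count, 2 of 100 splits gave as many as the 821 genes, a share under 0.05. The other gave 849 and put the 2-month slide 3 hearts together. Splits that leave slide aside therefore cannot exclude chance for this count. The real split gave 973 with slide as a fixed term, a fit that was not run for the other split. For the 151 shared genes the highest other split gave 0. This cannot exclude chance either. Other splits of the 1-month hearts called 0 genes on their own, so most splits could hardly share any, and slide was left aside. Chance is also not excluded for the interaction, where 55 of 100 splits gave as many as 644 genes at an unadjusted p under 0.05 after removal of the mean genotype difference, up to 3524 in a split that again parts slide 3 at 2 months. Nor is it for the correlation of 0.182 across genes, which 18 of 100 splits reached (highest 0.488), or for the 6 lists of the averaged comparison, which 67 of 100 reached (highest 17).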
